A study of Mus musculus with 6 samples.

How the data were processed

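RNA was measured by poly(A)-selected RNA sequencing in 6 libraries from mouse bone marrow-derived naive (M0) macrophages, 3 from cultures that received PBS and 3 from cultures that received PTEN at 100 ng/mL, all at 24 h. Per the labels' protocols, messenger RNA was captured on poly-T beads, fragmented, copied with random primers, amplified by PCR and sequenced on an Illumina NovaSeq. The protocols describe this preparation and also name a SMARTer kit, and whether the libraries keep strand is not given in the sources used here. The groups and the replicate numbers 1 to 3 were taken from the sample titles.

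Per the submitters' processing notes, fastp 0.22.0, HISAT2 2.1.0, HTSeq 0.9.1 and the build mm39 were used. The settings, the annotation release and the strand option of the counting are not given in the sources used here. Per the file headers, the authors deposited a read count and an FPKM value for each gene and library, in 1 table indexed by Ensembl gene identifiers. The deposited counts were whole numbers with different totals per library and were used as deposited. The authors' FPKM values equalled the count divided by a fixed gene length and by the column total, with a largest relative difference of 1.9e-07, and were used only to recover that gene length. The counts of genes that overlap, of antisense partners and of near-identical family members cannot be separated further, because the handling of shared reads is not stated.

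The table held 21907 lines after its header. Of these, 8 held spilled annotation text, named no gene and carried no counts, so their share of the counts was 0. The remaining 21899 lines were genes, of which 21795 had a symbol in a table of mouse gene names and 21807 (99.58%) were protein-coding in GENCODE release M21. At least 1 count was present for 15227 genes. No column of another series was present. GENCODE M21 is built on GRCm38, which is not the build of the deposited counts, so no coordinates are printed and the release was used only for gene types and for the GC content of transcripts.

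Total counts per library were 18533017, 15278279 and 15702269 for PBS replicates 1, 2 and 3, and 19591902, 17706351 and 17328344 for PTEN replicates 1, 2 and 3. A floor of 3 counts in a library corresponded to 0.153 to 0.196 CPM. Where a gene had 1 to 3 counts in a whole group, the ratio of counts between the groups is given with its exact 95% binomial interval, which covers counting error only, since PCR copies were not marked with molecular identifiers.

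The analysis used R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Figures were drawn with matplotlib 3.10.9. Genes were kept by the default expression filter of edgeR, which left 11575 genes holding at least 99.95% of the counts of each library. Library sizes were scaled by TMM, and CPM values use the scaled sizes. PTEN was compared with PBS by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over the 11575 genes, with group as the only term, 4 residual degrees of freedom and an adjusted p threshold of 0.05. The edgeR adjusted p values in the text come from this test, which is two-sided. Fold changes are log2 of PTEN over PBS, with the standard error computed as the absolute log2 fold change divided by the square root of F.

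Before the data were examined, 35 gene lists (699 genes, 693 of them with a row) were fixed, covering macrophage activation, interferon responses, antigen presentation, signalling, metabolism, stress, the cell cycle and markers of other bone marrow cells. Clec7a, Mx1, Mx2, Cxcl11, Ero1a and Ighm had no row and were not analysed here, and 2 list genes were matched through an older symbol. Aldoa stood under 2 identifiers, and both entered its list. Each list was tested against the other genes with camera on voom values, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 35 lists. The test was repeated with a correlation estimated for each list, and fry was run beside it.

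Genes to be named were also fixed beforehand. They were the 12 genes with the largest rise and the 12 with the largest fall among genes past the threshold with a mean of at least 5 CPM and no overlap between groups, leaving out predicted and clone names. Up to 4 members of each list with the smallest adjusted p, and 9 genes named whatever their values (Pten, Plxdc2, Jak2, Stat1, Il10, Arg1, Nos2, Tnf and Mrc1), completed the rule. Members outside this rule, among them Fosb, those that complete a small count and those that belong to the lists described under the additional observations, were chosen after their values were seen.

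Nothing in the labels says that the libraries of a group came from separate animals or cultures, so the p-values measure only the spread between these samples, which may be technical. No 2 libraries of a group agreed within sampling noise, since chi-square per degree of freedom was at least 4.56. The numbers 1 to 3 recur in both groups. Deviations from the group means across genes correlated between libraries of the same number at r = 0.368, 0.145 and 0.168, all above the limit of 0.1 set for pairing. PBS replicate 3 with PTEN replicate 2 (r = 0.148) and PBS replicate 2 with PTEN replicate 3 (r = 0.177) correlated as strongly, so meeting the limit rests on the number 1 libraries. Because deviations were centred within each group, a positive correlation of the number 1 libraries makes those among the others positive on average. In both number 1 libraries the deviations followed gene length in the same direction. Meeting the limit therefore does not show that the numbers mark a shared origin. The unpaired fit had been fixed as the one to report and was kept, and the fit with the replicate number as a block was an alternative.

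Other alternatives were median-of-ratios and upper-quartile scaling, no low-count filter, a filter of 5 CPM in 3 libraries, DESeq2, limma voom, a minimum absolute log2 fold change of 1, a test against a 1.2-fold change, and leaving out each library in turn. Removing a gene length trend from each library with a loess curve (span 0.5), with and without the block, and leaving out both number 1 libraries were added after the data were seen. The test was checked on simulated counts for the comparison of PTEN with PBS, over 11450 genes with 50 genes changed at each size. It recovered 20% of the genes changed 1.5-fold, 66% of those changed 2-fold, 98% of those changed 4-fold and 96% of those changed 8-fold, and called 9 unchanged genes. A further set, of the size of the S phase list, was lowered 1.5-fold to check the list test and enters none of these values. Far fewer genes were changed in the simulated counts than were called in the data, so the adjusted threshold was harder to pass there. Genes were drawn independently and without a gene length trend, so the check does not cover errors shared across the genes of a library.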

Results

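The transcriptome of mouse bone marrow-derived naive (M0) macrophages, cells grown from marrow precursors without a polarising stimulus, was profiled after 24 h with PBS or with PTEN at 100 ng/mL. PTEN is a phosphatase known inside cells as a brake on PI3K and AKT signalling, and here it was added to the cultures. Each group held 3 libraries, with 15278279 to 18533017 counted reads in the PBS group and 17328344 to 19591902 in the PTEN group. The only comparison in the design asks how the RNA profile of the macrophages differed between PTEN and PBS.

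Genes of inflammatory macrophage activation were far higher in the PTEN libraries. Acod1 (ENSMUSG00000022126), which makes itaconate, rose from 32.4 ± 6.07 CPM to 5938 ± 395 CPM (SD, n = 3 in each group), a log2 fold change of 7.52 ± 0.19 (SE; edgeR adjusted p = 8.62e-07). The transcription factor Mafb, which marks differentiated macrophages, fell from 302 ± 18.0 CPM to 46.2 ± 1.67 CPM (SD, n = 3; log2 fold change -2.71). Across the 11575 genes tested, 3527 (30.5%) changed at an adjusted p of 0.05, of which 1796 were higher and 1731 lower with PTEN. At an absolute log2 fold change of at least 1, 961 genes were higher and 760 lower. The values of the groups did not overlap for 3518 of the changed genes (99.7%) and for 5497 of all tested genes (47.5%), where chance gives 10%. The first principal component of log2 CPM took 77.2% of the variance and separated the groups.

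**Figure D1:**
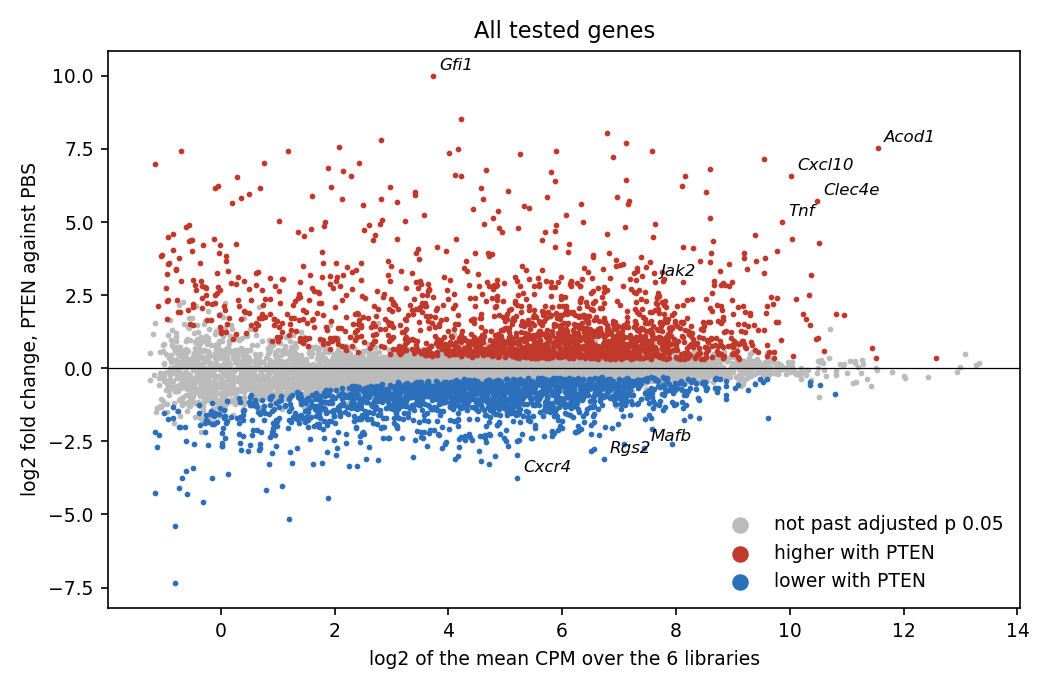
Each point is 1 of the 11575 tested genes, with the log2 of its mean CPM over the 6 libraries on the x axis and its log2 fold change, PTEN against PBS, on the y axis. The 1796 genes higher with PTEN (red) reach larger changes than the 1731 lower genes (blue), and the value plotted for Gfi1 is a fitted one that rests on 1 count in the PBS group.

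The number of changed genes depended most on PBS replicate 1, without which it was 6183. When any other library was left out it fell, to between 2304 (without PTEN replicate 3) and 3021 (without PBS replicate 3). Each of these fits holds 1 library fewer, so a call lost in one of them need not rest on the library left out. Upper-quartile scaling called 38.4% of 3821 changed genes higher, against 50.9% with TMM, and moved the median log2 fold change of all genes from -0.039 to -0.17, so directions of small changes are relative to the scaling.

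Cytokines and enzymes of classical activation rose together. Of 19 measured proinflammatory mediators, 18 rose (18 when adjusted over the list alone), with a median log2 fold change of 5.82, or 6.09 when Csf2, Csf3 and Il12a, each at 1 or 2 counts in the PBS group, are set to their count ratios. Without PBS replicate 3 the median was 6.48, over 20 members. The camera adjusted p was 3.6e-16, and the adjusted p = 0.19 with an estimated correlation. Il12b, a subunit of interleukin-12, rose from 0.677 ± 0.0573 to 118 ± 1.52 CPM (SD, n = 3), and the interleukin Il1b from 2.23 ± 0.337 to 382 ± 58.4 CPM. Nos2, the inducible nitric oxide synthase, rose from 1.6 ± 0.382 to 238 ± 43.9 CPM (log2 fold change 7.22 ± 0.24 SE). Tnf, already present in PBS at 56.7 ± 8.97 CPM, reached 1811 ± 108 CPM (log2 fold change 5 ± 0.16 SE; edgeR adjusted p = 1.31e-06). Cd80, a co-stimulatory ligand, was the member that did not pass, with a log2 fold change of -0.01.

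All 24 members of the list of NF-kB feedback and target genes rose (24 when adjusted over the list alone; median log2 fold change 3.02). The camera adjusted p of this list was 2.6e-24, and the adjusted p = 0.087 with an estimated correlation. Icam1, an adhesion receptor for leukocytes, rose from 103 ± 3.38 to 1653 ± 70.1 CPM (SD, n = 3), and Tlr2, a receptor for bacterial lipoproteins, from 98.2 ± 8.12 to 1251 ± 37.3 CPM. Nfkbie, an inhibitor of NF-kB, and Sod2, the mitochondrial superoxide dismutase, rose by log2 fold changes of 3.54 and 3.94.

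Of 16 measured chemokines, 13 rose and Cxcl14 fell, while 2 did not pass (14 rose and 1 fell when adjusted over the list alone). Their median log2 fold change was 3.80 (camera adjusted p = 5.1e-11; adjusted p = 0.24 with an estimated correlation), and it was 2.92 over 18 members with no low-count filter. The neutrophil-attracting chemokine Cxcl2 rose from 10.4 ± 0.769 to 1493 ± 48.8 CPM (SD, n = 3; log2 fold change 7.16), with Cxcl1 at 7.69 and Cxcl3 at 8.05. Cxcl1, Cxcl2 and Cxcl3 are close paralogs, so reads could be shared among them and their separate values are uncertain. The fall of Cxcl14 (log2 fold change -0.64) did not pass without PTEN replicate 1 (edgeR adjusted p = 0.054) or PTEN replicate 2 (edgeR adjusted p = 0.0604).

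All 27 members of a list of endotoxin-inducible genes rose (27 when adjusted over the list alone), with a median log2 fold change of 5.49. The camera adjusted p was 4.7e-23, and the adjusted p = 0.19 with an estimated correlation. Clec4e, a receptor for damaged cells and mycobacterial glycolipid, rose from 53.2 ± 6.20 to 2793 ± 144 CPM (SD, n = 3), and Gpr84, a receptor for medium-chain fatty acids, from 5.38 ± 0.260 to 285 ± 12.6 CPM. The prostaglandin E synthase Ptges rose from 3.14 ± 0.406 to 277 ± 25 CPM. Of the 27 members, 8 also stand in other lists.

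**Figure D2:**
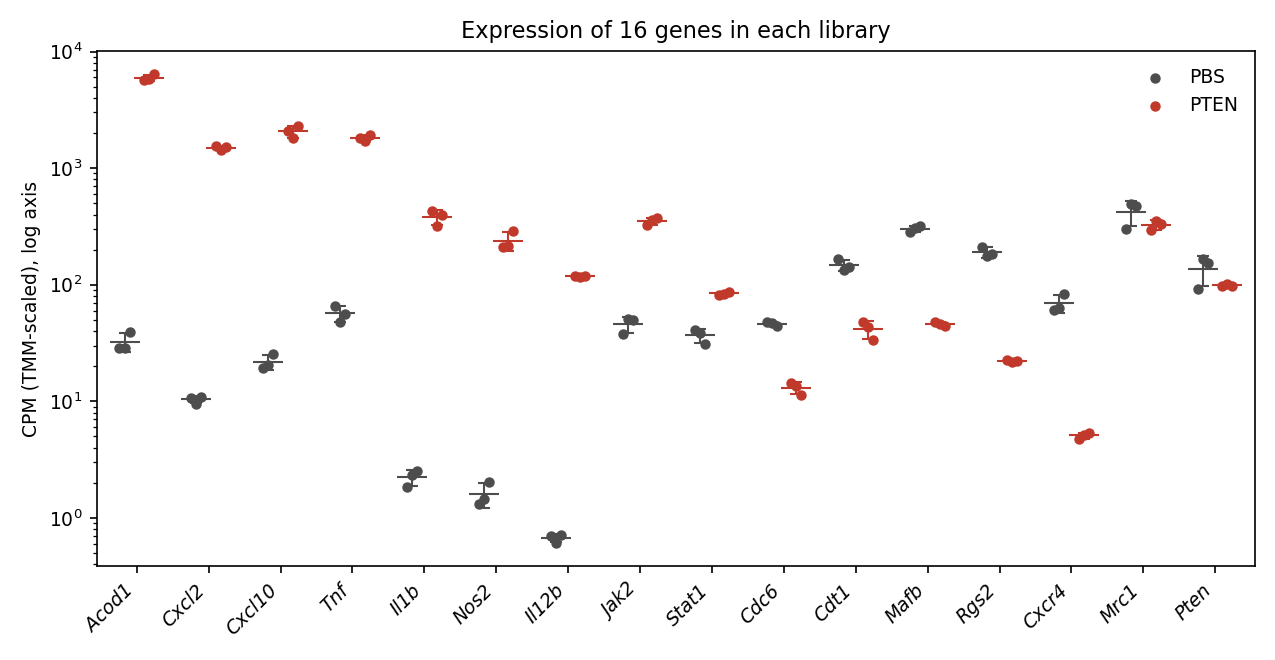
CPM of 16 genes on a log axis in each library, with points for single libraries, horizontal marks for group means and bars for 1 SD (n = 3; PBS grey, PTEN red). The groups lie apart for Acod1 to Cxcr4, in order along the x axis, and overlap for Mrc1 and Pten.

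Interferon-responsive genes were the other large group to rise. Of 40 measured type I interferon-stimulated genes, 37 rose (38 when adjusted over the list alone), with a median log2 fold change of 2.03 (camera adjusted p = 4.7e-23; adjusted p = 0.19 with an estimated correlation). Ifi205 rose from 1.81 ± 0.444 to 105 ± 5.25 CPM (SD, n = 3), Oasl1 from 27.3 ± 1.49 to 291 ± 30.3 CPM and Ifit3 from 49.0 ± 3.79 to 389 ± 32.8 CPM. Ifit3 and Ifit3b are near-identical copies, so their separate values are uncertain. Of 27 measured interferon-gamma and STAT1 target genes, 25 rose, Irf8 fell (log2 fold change -0.91) and Gbp8 did not pass, with the same counts when adjusted over the list alone. The median log2 fold change of this list was 2.97 (camera adjusted p = 2.5e-15; adjusted p = 0.19 with an estimated correlation). The T cell-attracting chemokine Cxcl10 rose from 21.8 ± 3.32 to 2066 ± 248 CPM, and the guanylate-binding protein gene Gbp2 from 16.7 ± 3.31 to 371 ± 26.3 CPM, although the Gbp genes resemble one another. Jak2, a kinase of cytokine receptors, rose from 45.9 ± 7.26 to 350 ± 25.1 CPM (log2 fold change 2.93 ± 0.15 SE; edgeR adjusted p = 1.02e-05). Its partner transcription factor Stat1 rose from 36.9 ± 5.15 to 84.2 ± 2.86 CPM (log2 fold change 1.19 ± 0.13 SE; edgeR adjusted p = 0.000427).

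Part of the antigen presentation genes rose. Of 19 measured genes of MHC class I presentation, 13 rose (14 when adjusted over the list alone), with a median log2 fold change of 1.06 (camera adjusted p = 1.1e-07; adjusted p = 0.31 with an estimated correlation). Tap1, a subunit of the peptide transporter, rose from 110 ± 3.14 to 270 ± 17.7 CPM (SD, n = 3), and the non-classical gene H2-Q7, whose reads could be shared with related H2 genes, rose by a log2 fold change of 2.25. Of 12 genes of MHC class II presentation, H2-Ab1, H2-Eb1, H2-Aa, H2-Ob and the master regulator Ciita rose (7 when adjusted over the list alone), and 7 did not pass. Of this list 8 rose without PBS replicate 1. H2-Ab1 rose from 37.3 ± 11 to 149 ± 14 CPM and Ciita from 5.68 ± 2.66 to 16.8 ± 3.13 CPM. The class II list had a median log2 fold change of 0.54 (camera adjusted p = 0.029; adjusted p = 0.7 with an estimated correlation). It did not pass without PBS replicate 2 (adjusted p = 0.054) or with the stricter low-count filter (adjusted p = 0.064).

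The 12 largest rises also held genes outside these lists. Gfi1, a transcriptional repressor of blood cells, was at 1 count in the PBS group and 1347 counts in the PTEN group, a ratio of 1400 (95% interval 251 to 55400). Cd247, the zeta chain of the T cell receptor complex, was at 3 and 716 counts, a ratio of 248 (95% interval 84.7 to 1210). The PBS counts of both genes lay in PBS replicate 1, without which their fitted log2 fold changes became 11.8 and 10.89, from 9.99 and 7.79. Shisa3 rose from 0.0941 ± 0.0317 to 37.0 ± 4.29 CPM (SD, n = 3), Zfp811 from 0.191 ± 0.0448 to 32.2 ± 2.81 CPM, and the Ras activator Rasgrp1 from 0.471 ± 0.237 to 76.6 ± 6.96 CPM. Lad1 rose from 0.197 ± 0.195 to 35.9 ± 4.4 CPM, with a log2 fold change of 7.51 that became 8.64 without PBS replicate 3. Shisa3, Zfp811 and Lad1 were at 5, 10 and 10 counts in the whole PBS group, so the sizes of their rises are uncertain. Among the 12 largest falls, Cxcr4, the receptor for Cxcl12, fell from 69.2 ± 12 to 5.10 ± 0.301 CPM (log2 fold change -3.76 ± 0.17 SE; edgeR adjusted p = 5.13e-06). The oxysterol receptor gene Gpr183 fell from 42.9 ± 4.33 to 4.70 ± 0.924 CPM, and Rgs2, a regulator of G protein signalling, from 190 ± 19.9 to 22.1 ± 0.340 CPM (log2 fold change -3.10 ± 0.12 SE). The remaining 9 were Etl4, Zfp395, Mex3b, Fam214a, Zfyve28, Slc26a11, Rnf144b, Rnf150 and Arrdc3, with log2 fold changes between -3.35 and -2.85.

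Genes of DNA replication were lower with PTEN. Of 24 measured S phase genes, 18 fell (20 when adjusted over the list alone), with a median log2 fold change of -0.66 (camera adjusted p = 4.3e-09; adjusted p = 0.19 with an estimated correlation). The origin licensing factors Cdc6 and Cdt1 fell from 46.4 ± 1.77 to 13.1 ± 1.45 CPM and from 147 ± 16.4 to 41.5 ± 7.25 CPM (SD, n = 3). Uhrf1 and E2f1 fell by log2 fold changes of -0.90 and -0.83. Of 24 genes of G2 and M phase, Kif23, Ttk, Bub1b and Aurkb fell (4 when adjusted over the list alone) and 20 did not pass. The number that fell was 12 without PBS replicate 1 (camera adjusted p = 0.0063), 8 with upper-quartile scaling (camera adjusted p = 0.012) and 1 each without PTEN replicates 2 and 3. The median log2 fold change of this list was -0.21 (camera adjusted p = 0.033; adjusted p = 0.69 with an estimated correlation). It did not pass without PBS replicate 3 (adjusted p = 0.099), PTEN replicate 2 (adjusted p = 0.067) or PTEN replicate 3 (adjusted p = 0.057). Ttk, Bub1b and Aurkb lost their calls without PTEN replicate 3 (edgeR adjusted p = 0.0685, 0.0553 and 0.0977). All 3 also did without PTEN replicate 2 (0.0665, 0.0514 and 0.129), Bub1b without PTEN replicate 1 (0.0631) and Aurkb without PBS replicate 3 (0.0507), while Kif23 passed in each of these fits.

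Markers of macrophage identity moved in both directions, and their list passed fry as lower (adjusted p = 0.03) but not camera. Of 20 measured, 8 fell and 5 rose (8 and 6 when adjusted over the list alone; median log2 fold change -0.17; camera adjusted p = 0.44). The balance depended on the libraries, with 9 higher, 8 lower and a median of 0.01 without PBS replicate 1. In each of the 5 fits that left out another library 3 were higher and 4 to 7 lower, and with upper-quartile scaling 3 were higher and 8 lower. Mafb and the myeloid transcription factor Cebpa (from 103 ± 15.6 to 25.2 ± 3.77 CPM; SD, n = 3) were among those that fell. The 5 that rose were Adgre1, which encodes F4/80 and reached 1936 ± 143 CPM from 939 ± 86.9 CPM, the transcription factors Cebpb and Spi1, the CSF1 receptor gene Csf1r and the Fc receptor gene Fcgr1. The calls of Csf1r and Fcgr1 were lost in every fit that left out a library other than PBS replicate 1 (edgeR adjusted p from 0.0647 to 0.18) and with upper-quartile scaling (edgeR adjusted p = 0.134 and 0.253). That of Fcgr1 was lost also with the replicate block (edgeR adjusted p = 0.0616). Of 22 scavenging and phagocytosis receptors, 6 rose and 7 fell (6 and 7 when adjusted over the list alone; median log2 fold change -0.13; camera adjusted p = 0.91; fry adjusted p = 0.014, as higher). The oxidised lipoprotein receptor gene Olr1 rose from 0.0936 ± 0.0298 to 9.65 ± 0.676 CPM, Marco from 4.28 ± 2.17 to 113 ± 2.96 CPM, and the inhibitory Fc receptor gene Fcgr2b from 29.6 ± 0.537 to 279 ± 27.6 CPM. Olr1 was at 5 counts in the whole PBS group, so the size of its rise is uncertain. Mertk, a receptor for dying cells, fell by a log2 fold change of -1.59.

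Markers of alternative activation moved both ways, and their list passed fry as higher (adjusted p = 0.035) but not camera. Of 17 measured, Ccl17, Ccl22, Egr2, Flt1 and Tgm2 rose, Klf4, Clec10a and Il4ra fell, and 9 did not pass (6 rose and 5 fell when adjusted over the list alone; median log2 fold change -0.32; camera adjusted p = 0.89). Of 18 measured without PBS replicate 1, 6 rose and 7 fell. Ccl22 rose from 1.68 ± 0.693 to 78.7 ± 9.92 CPM (SD, n = 3). Ccl17 was at 1 count in the PBS group and 99 counts in the PTEN group, a ratio of 103 (95% interval 18.1 to 4110). Without PBS replicate 1, which held that count, its fitted log2 fold change became 8.03, from 6.22. Klf4 fell from 27.9 ± 2.89 to 8.09 ± 1.53 CPM. The fall of Il4ra, the interleukin-4 receptor, was lost in every fit that left out a library other than PBS replicate 1 (edgeR adjusted p from 0.0691 to 0.174) and with the replicate block (edgeR adjusted p = 0.0569). The rise of Flt1 was lost without PTEN replicate 3 (edgeR adjusted p = 0.0535). Arg1 was near 1 CPM in both groups (0.746 ± 0.203 and 0.552 ± 0.0587 CPM) and Il10 was at 8.73 ± 0.949 and 7.94 ± 1.92 CPM. Neither passed (edgeR adjusted p = 0.454 and 0.665). Mrc1, the mannose receptor gene, was at 421 ± 105 CPM in PBS and 326 ± 30.3 CPM in PTEN and did not pass (log2 fold change -0.37; edgeR adjusted p = 0.197). It passed without PBS replicate 1 (log2 fold change -0.56; edgeR adjusted p = 6.8e-06, in a range of 4.98e-07 to 0.449 over the alternatives) and with the gene length trend removed in the fit with the replicate block (log2 fold change -0.34; edgeR adjusted p = 0.0107).

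Transcripts of Pten itself were at 137 ± 39.6 CPM in PBS and 98.6 ± 2.52 CPM in PTEN (SD, n = 3), with a log2 fold change of -0.48 ± 0.21 (SE) that did not pass (edgeR adjusted p = 0.132). Without PBS replicate 1 the log2 fold change of Pten was -0.70 and passed (edgeR adjusted p = 1.94e-07, in a range of 1.58e-08 to 0.344 over the alternatives). Upper-quartile scaling also brought it past the threshold (log2 fold change -0.59; edgeR adjusted p = 0.041), as did removing the gene length trend from each library, without the replicate block (log2 fold change -0.51; edgeR adjusted p = 0.00258) and with it (log2 fold change -0.50; edgeR adjusted p = 0.00165). Plxdc2, a membrane receptor gene, was at 12.3 ± 2.35 and 14.2 ± 1.34 CPM and did not pass (log2 fold change 0.20 ± 0.18 SE; edgeR adjusted p = 0.437).

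Among 24 measured FOXO target genes, which AKT represses through FOXO factors, 11 fell and 4 rose (11 and 6 when adjusted over the list alone), with a median log2 fold change of -0.46. The list did not pass (camera adjusted p = 0.093; adjusted p = 0.72 with an estimated correlation). With the preset correlation it passed without PBS replicate 1 (adjusted p = 0.012, with 16 lower and 6 higher), without PTEN replicate 2 (adjusted p = 0.041) and with no low-count filter (adjusted p = 0.037). The sphingosine-1-phosphate receptor gene S1pr1 fell from 74.3 ± 6.53 to 14.1 ± 1.17 CPM (SD, n = 3) and the thioredoxin inhibitor gene Txnip from 191 ± 12 to 86.6 ± 4.63 CPM. Cited2, Trib1, Gadd45a and Sell were the 4 that rose, with Cited2 going from 163 ± 0.706 to 406 ± 7.62 CPM. Sell lost its call without PTEN replicate 1, 2 or 3 (edgeR adjusted p = 0.0584, 0.0741 and 0.0699). Of 23 immediate early genes, 7 rose and 8 fell (7 and 9 when adjusted over the list alone; median log2 fold change -0.24; camera adjusted p = 0.89). Junb rose from 223 ± 40.6 to 798 ± 39.1 CPM, and Dusp2 and Ier3 rose by log2 fold changes of 2.88 and 2.13. Klf4 fell by a log2 fold change of -1.79, and the largest change of this list was the fall of Fosb from 3.29 ± 1.21 to 0.182 ± 0.263 CPM. The PTEN value of Fosb lies near the floor of 3 counts in a library, so the size of its fall is uncertain. The log2 fold change of Fosb, -4.15, became -3.53 without PTEN replicate 1 and -6.46 without PTEN replicate 2.

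Stress response lists did not pass camera as groups with all 6 libraries. By fry the NRF2 (adjusted p = 0.0081) and heat shock (adjusted p = 0.035) lists passed as higher. The ATF4 (fry adjusted p = 0.088) and unfolded protein response (fry adjusted p = 0.18) lists did not. Of 20 NRF2 target genes, Slc7a11, Sqstm1, Txnrd1, Gsr and Me1 rose and Osgin1 fell (5 and 1 when adjusted over the list alone; median log2 fold change 0.11; camera adjusted p = 0.22). With PBS replicate 1 left out, 10 rose and 3 fell and the NRF2 list passed with the preset correlation (adjusted p = 0.034). With all libraries and an estimated correlation the adjusted p was 0.89. The cystine transporter gene Slc7a11 rose from 3.19 ± 1.64 to 157 ± 20.7 CPM (SD, n = 3) and the autophagy receptor gene Sqstm1 from 593 ± 50.3 to 1898 ± 76.0 CPM. Of 19 genes of the ATF4 response, Slc7a11, Nupr1, Phgdh, Slc7a5 and Mthfd2 rose (5 when adjusted over the list alone; median log2 fold change 0.18; camera adjusted p = 0.22). Of 19 genes of the unfolded protein response, Herpud1, Syvn1 and Hyou1 rose and Dnajb9 fell (3 and 1 when adjusted over the list alone; median log2 fold change 0; camera adjusted p = 0.79). Herpud1 rose from 49.5 ± 8.34 to 162 ± 8.56 CPM. Of 12 heat shock genes, the near-identical pair Hspa1a and Hspa1b and the co-chaperone gene Dnaja1 rose (3 when adjusted over the list alone; median log2 fold change 0.12; camera adjusted p = 0.39). In the fit without PBS replicate 1, 9 ATF4 response genes rose, 6 genes of the unfolded protein response rose and 3 fell, and 5 heat shock genes rose and 1 fell. Leaving out any other library left 2 or 3 ATF4 genes higher, and leaving out PBS replicate 3 or any PTEN replicate left 1 gene of the unfolded protein response higher. With upper-quartile scaling 2 ATF4 genes rose and 1 fell, and 1 gene of the unfolded protein response rose and 3 fell. The calls of Phgdh, Mthfd2, Hyou1, Dnajb9 and Dnaja1 were lost in every fit that left out a library other than PBS replicate 1, and those of Me1, Slc7a5 and Syvn1 in 4 of these 5 (edgeR adjusted p from 0.0523 to 0.16 over the 8 genes). With upper-quartile scaling Me1, Phgdh, Slc7a5, Mthfd2, Syvn1, Hyou1 and Dnaja1 did not pass either (edgeR adjusted p from 0.0527 to 0.167).

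Metabolic lists did not pass as groups with all 6 libraries. Of 27 measured entries for glycolysis and hypoxia, the glucose transporter gene Slc2a1, Pfkl, Pfkfb3, Slc16a3 and P4ha1 rose and Ndrg1, Hk1, Ankrd37 and 1 of the 2 entries for Aldoa fell (6 and 4 when adjusted over the list alone; median log2 fold change -0.01; camera adjusted p = 0.89). Of these entries 11 rose and 8 fell without PBS replicate 1, and 5 rose and 7 fell with upper-quartile scaling. In the 5 fits that left out another library 3 to 7 rose and 0 to 2 fell. Slc2a1 rose from 52.3 ± 11.5 to 160 ± 16.3 CPM (SD, n = 3). Of 28 nuclear genes of oxidative phosphorylation, the cytochrome c gene Cycs rose (0 when adjusted over the list alone, 1 at an unadjusted p under 0.05, and 1 each with DESeq2 and limma voom). In this list 12 rose without PBS replicate 1, where it passed with the preset correlation (adjusted p = 0.024 against 0.99 with all libraries). The adjusted p = 1 with an estimated correlation and all libraries. None of 38 cytosolic ribosomal protein genes passed edgeR's quasi-likelihood test (0 when adjusted over the list alone, 0 at an unadjusted p under 0.05, 0 with DESeq2 and 0 with limma voom; camera adjusted p = 0.72). Without PBS replicate 1, 22 of the ribosomal genes were higher and the list passed as higher (adjusted p = 0.0011). Without PBS replicate 3 it passed as lower (adjusted p = 0.038), both with the preset correlation, while with an estimated correlation and all libraries the adjusted p was 0.98. Likewise 0 of 10 mitochondrially encoded genes passed in edgeR, at an unadjusted p under 0.05, in DESeq2 and in limma voom (0 when adjusted over the list alone; median log2 fold change 0.07; camera adjusted p = 0.89). The calls of Cycs and Hk1 were lost in every fit that left out a library other than PBS replicate 1, and those of Pfkfb3 and Ankrd37 in 4 of these 5. That of Ndrg1 was lost without PTEN replicate 2 or 3 and that of P4ha1 without PTEN replicate 1 (edgeR adjusted p from 0.0515 to 0.239 over the 6 genes). Hk1 did not pass with the replicate block either (edgeR adjusted p = 0.0595), nor Cycs with upper-quartile scaling (edgeR adjusted p = 0.13). The call of Hk1 was also lost with median-of-ratios scaling (edgeR adjusted p = 0.053) and with no low-count filter (edgeR adjusted p = 0.116).

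Of 22 cholesterol synthesis genes, Hmgcr, the rate-limiting reductase, Ldlr and Srebf2 rose and Dhcr7, Msmo1 and Acat2 fell (3 and 2 when adjusted over the list alone; median log2 fold change -0.18; camera adjusted p = 0.89). Of these 6 rose and 8 fell without PBS replicate 1, 3 rose and 7 fell with upper-quartile scaling, and 2 rose and 1 fell without PBS replicate 2 or any PTEN replicate. Of 14 LXR target genes, Nr1h3, which encodes LXR alpha and rose from 29.6 ± 4.16 to 94.6 ± 9.69 CPM (SD, n = 3), and the cholesterol exporter gene Abca1 rose, and Scd2 and Smpdl3a fell (2 and 3 when adjusted over the list alone; median log2 fold change -0.22; camera adjusted p = 0.63). The LXR targets that fell were 7 without PBS replicate 1, 5 with upper-quartile scaling and 4 with the replicate block. The call of Acat2 was lost in every fit that left out a library other than PBS replicate 1 and those of Srebf2, Msmo1, Abca1 and Smpdl3a without PBS replicate 2 or any PTEN replicate (edgeR adjusted p from 0.0521 to 0.2). Acat2 did not pass with the replicate block either (edgeR adjusted p = 0.0597). Of 28 lysosomal genes, the protease gene Ctsc rose from 402 ± 38.6 to 987 ± 80.4 CPM. Tfeb, a transcription factor of lysosome biogenesis, Atp6v0d2, Gla and Ctsl fell (1 and 3 when adjusted over the list alone; median log2 fold change -0.19; camera adjusted p = 0.11; fry adjusted p = 0.042, as lower). Of the lysosomal genes 5 rose and 10 fell without PBS replicate 1, and 1 rose and 7 fell with upper-quartile scaling. Ctsl did not pass without PBS replicate 3 or any PTEN replicate (edgeR adjusted p from 0.0538 to 0.201). Its call was also lost with median-of-ratios scaling, no low-count filter or the length trend removed (edgeR adjusted p from 0.0529 to 0.0755). In limma voom the adjusted p of Ctsl was 0.055. Of 25 genes of matrix remodelling and angiogenesis, 9 rose and Plau, Mmp8, Adam8 and Timp2 fell (9 and 4 when adjusted over the list alone; median log2 fold change 0.09; camera adjusted p = 0.44; fry adjusted p = 0.011, as higher). This median was -0.13 without PBS replicate 1, where 9 rose and 7 fell, and -0.22 without PTEN replicate 1. The membrane-bound metalloproteinase gene Mmp14 rose from 21.2 ± 5.04 to 751 ± 34.6 CPM, and Adamts4 from 0.354 ± 0.282 to 34.4 ± 2.31 CPM, with a log2 fold change of 6.62 that became 7.42 without PBS replicate 3.

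**Figure D3:**
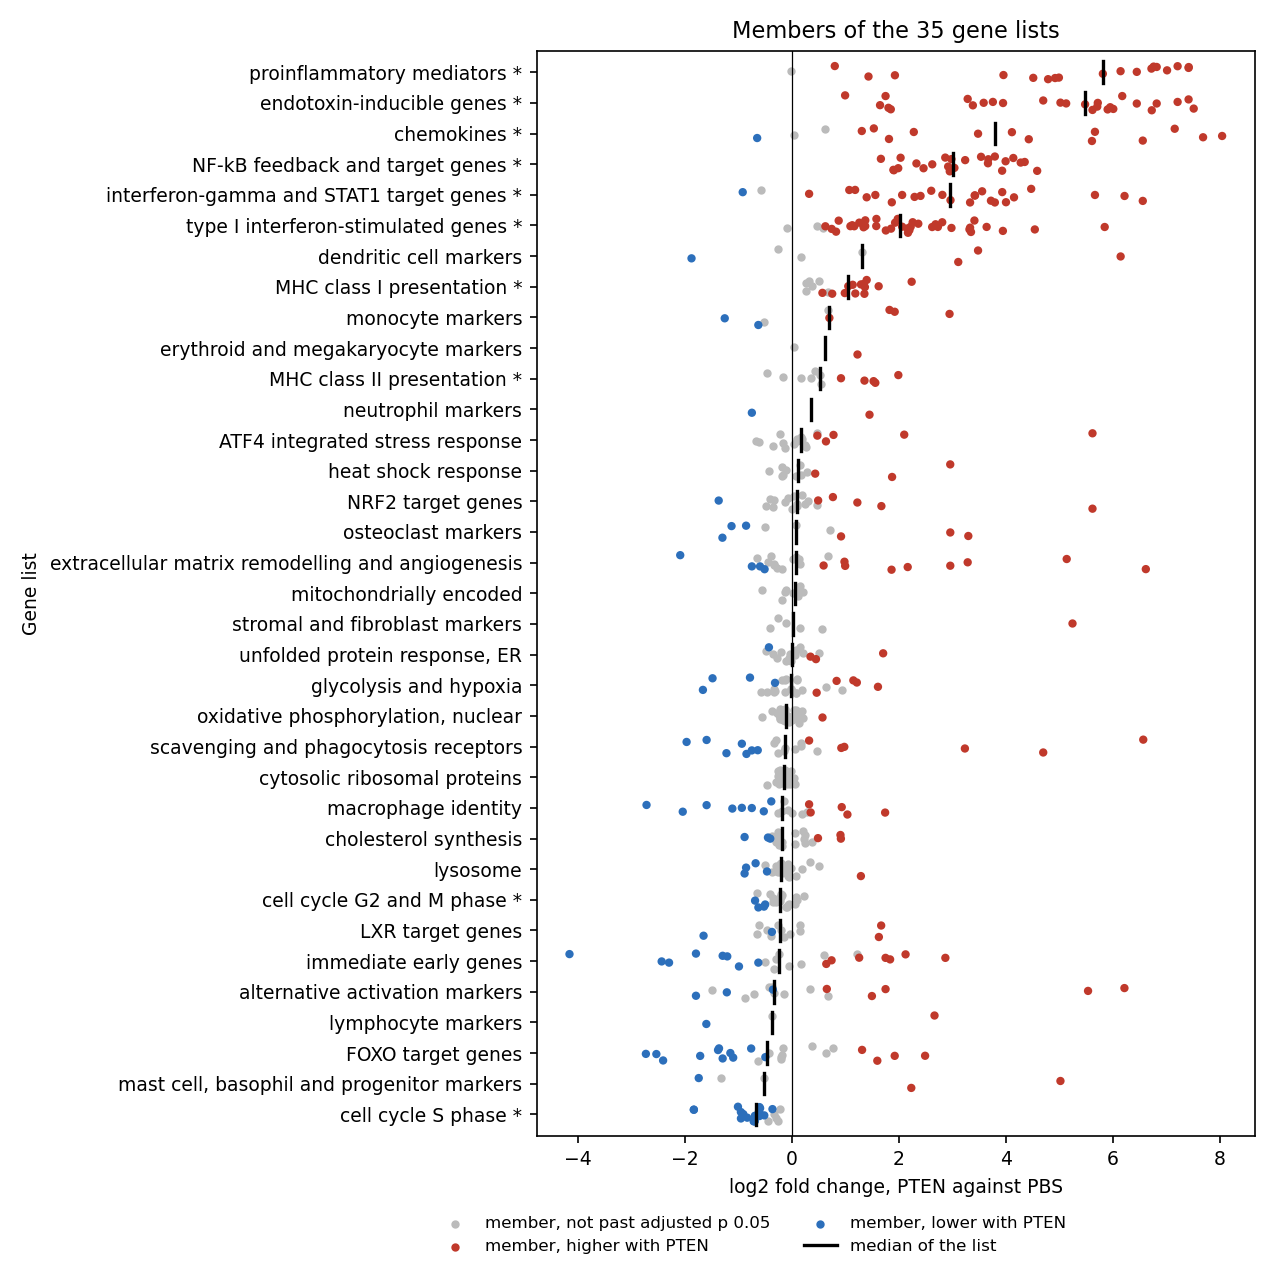
Log2 fold change, PTEN against PBS, of every measured member of the 35 gene lists (x axis), with lists in rows ordered by their median (black bar), members higher with PTEN in red, lower in blue and not past the threshold in grey. A star marks the 10 lists past a camera adjusted p of 0.05, from proinflammatory mediators (median 5.82) to S phase genes (median -0.66), of which 0 pass with an estimated correlation.

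Markers of other bone marrow cells were mostly low and moved in both directions. Of 7 measured dendritic cell markers, Cd83, Fscn1 and Xcr1 rose and Batf3 fell (3 and 1 when adjusted over the list alone; median log2 fold change 1.32; camera adjusted p = 0.093; fry adjusted p = 0.00037, as higher). This list passed camera without PTEN replicate 1 (adjusted p = 0.037), with upper-quartile scaling (adjusted p = 0.047), with no low-count filter (adjusted p = 0.02) and with the stricter filter (adjusted p = 0.023), all with the preset correlation. The adjusted p = 0.36 with an estimated correlation and all libraries. The dendritic cell median was 0.49 over 10 members without PBS replicate 1. Cd83 rose from 13 ± 2.02 to 113 ± 6.23 CPM (SD, n = 3), and the actin-bundling gene Fscn1 from 0.627 ± 0.492 to 46.8 ± 3.42 CPM. Of 8 monocyte markers, Itgal, Vcan, Spn and Sell rose and Ccr2 and Nr4a1 fell (4 and 2 when adjusted over the list alone; median log2 fold change 0.70; camera adjusted p = 0.36; fry adjusted p = 0.048, as higher). Of 9 osteoclast markers, Mmp9, Car2 and Ocstamp rose and Nfatc1, Itgb3 and Atp6v0d2 fell (4 and 4 when adjusted over the list alone; median log2 fold change 0.09; camera adjusted p = 0.99). Of 2 measured neutrophil markers, Csf3r rose and Mmp8 fell (1 and 1 when adjusted over the list alone; median log2 fold change 0.36; camera adjusted p = 0.89). Over 3 members the neutrophil median was 1.29, 1.45, 1.65 and 1.51 without PBS replicate 1, 2 or 3 or PTEN replicate 2. Among 5 markers of mast cells, basophils and progenitors, Hdc and Gata2 rose and Il1rl1 fell (2 and 3 when adjusted over the list alone; median log2 fold change -0.52; camera adjusted p = 0.99). Pdgfrb rose among 6 stromal markers (1 when adjusted over the list alone; median log2 fold change 0.03; camera adjusted p = 0.78). Lck rose and Cd79b fell among 3 lymphocyte markers (1 and 1; median -0.37; camera adjusted p = 0.89). Ppbp rose among 2 erythroid and megakaryocyte markers (1; median 0.63; camera adjusted p = 0.64; fry adjusted p = 0.033, as higher). Medians of these small lists depended on which members were measured. With no low-count filter they were 0.73 over 9 lymphocyte markers, -0.38 over 6 erythroid and megakaryocyte markers and 0.19 over 8 mast cell, basophil and progenitor markers, and the last was 2.24 over 2 markers with the stricter filter. The osteoclast median was -0.51 over 7 markers with the stricter filter, and the stromal median -0.38 without PTEN replicate 1. The calls of Nr4a1, Mmp8 and Ppbp were lost in every fit that left out a library other than PBS replicate 1, those of Ocstamp, Batf3, Sell and Cd79b in at least 3 of these 5, and that of Lck without PTEN replicate 1 (edgeR adjusted p from 0.0535 to 0.139 over the 8 genes). Ocstamp did not pass with the replicate block or with upper-quartile scaling either (edgeR adjusted p = 0.0554 and 0.0627). Without PBS replicate 1 the log2 fold changes of Fscn1, Xcr1 and Hdc became 6.98, 4.74 and 5.89, from 6.15, 3.49 and 5.03. Without PBS replicate 2 that of Lck became 3.33 from 2.67.

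The median, the mean and the test of a list differed in sign for alternative activation (-0.32, 0.53 and higher), scavenging receptors (-0.13, 0.39 and lower), glycolysis and hypoxia (-0.01, 0.03 and higher), oxidative phosphorylation (-0.10, -0.06 and higher), mitochondrially encoded genes (0.07, -0.02 and higher), lymphocyte markers (-0.37, 0.24 and lower) and mast cell, basophil and progenitor markers (-0.52, 0.74 and lower). Of the 35 lists, 10 passed with the preset correlation, 8 of them higher and 2 lower. With estimated correlations 0 passed camera, with 7 at an unadjusted p under 0.05, and fry, which asks whether a list's genes move one way without comparing them with other genes, called 21. The number of lists is a weak measure, since it ran from 0 to 21 with the test used. Of the 10 splits of the 6 libraries into 3 and 3, 8 gave as many lists with the preset correlation as the real groups. Every split other than the real one keeps part of the group difference, so this share does not test how far the number reflects it.

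PBS replicate 1 stood apart from the other PBS libraries. Its log2 CPM correlated with those of PBS replicates 2 and 3 at r = 0.968 and 0.964 across genes, which are not independent replicates, while the other pairs within a group ranged from 0.990 to 0.992. The difference followed gene length. Across 9790 genes, genes of up to 3020 bp had a median log2 difference of 0.45 between PBS replicate 1 and the mean of the other PBS libraries. For genes of at least 7079 bp it was -0.57. In PTEN replicate 1 the corresponding differences were 0.13 and -0.12. The ribosomal, oxidative phosphorylation, NRF2 and FOXO target lists, and the genes Pten and Mrc1, did not pass with all 6 libraries in the test fixed before the data were examined and passed without this library. Pten, Mrc1 and the FOXO list also passed in at least 1 setting that kept it, and the NRF2 list passed as higher by fry (adjusted p = 0.0081). With this library kept, the ribosomal list passed only without PBS replicate 3 and as lower, opposite to its direction without PBS replicate 1.

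**Figure D4:**
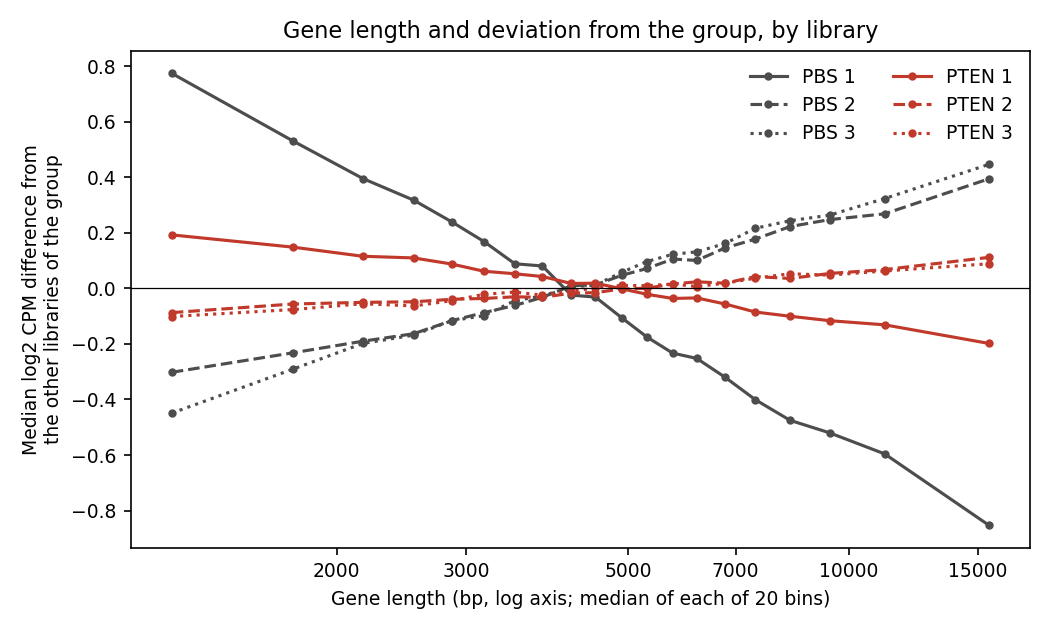
Median log2 CPM difference of each library from the mean of the other libraries of its group (y axis) over 20 bins of gene length (x axis, bp on a log scale), across 9790 genes. PBS replicate 1 goes from 0.775 in the bin of shortest genes to -0.853 in the bin of longest genes, and PTEN replicate 1 follows the same direction less steeply.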

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

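The settings that remove the length trend or leave out both number 1 libraries were chosen after seeing the data. The 3527 changed genes (1796 higher, 1731 lower) ranged from 2304 to 6183 when 1 library was left out, with 1259 to 3114 higher and 1043 to 3069 lower, and the 10 lists from 9 to 14. Leaving out both number 1 libraries gave 6221 genes (3104 higher, 3117 lower), and removing the length trend with the replicate block gave 2829 higher genes. Requiring an absolute log2 fold change of at least 1 left 1721 genes (961 higher, 760 lower), fewer by construction. The median of the proinflammatory list, 5.82, ranged from 5.40 to 6.48 with 1 library left out and was 5.11 without both number 1 libraries. With an estimated correlation 0 lists passed, and 21 passed with fry. Where these values moved, the cause was not tested, except for the fold minimum. The other settings kept all 3 counts within 1.5 times, from 2669 genes tested against a 1.2-fold change to 4682 with the length trend removed. No changed gene switched sign in any setting that refits the model.

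The replicate block gave 4000 changed genes, 3425 of them shared with the fit without it, and 10 lists. Beyond the calls of Il4ra, Fcgr1, Acat2, Hk1 and Ocstamp, the block changed no other call of a named gene or list. With no low-count filter Il4ra, Fcgr1, Dnajb9, Msmo1, Acat2 and Smpdl3a also lost their calls (edgeR adjusted p from 0.0543 to 0.112). So did Mmp8, Dnajb9, Dnaja1 and Smpdl3a with the length trend removed (0.0654 to 0.128), and Acat2 with that and the block (0.072). Mthfd2 lost its call with the stricter filter (0.0503) and Ocstamp without both number 1 libraries (0.0874).

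Over 16 settings and 217 genes, 3250 of 3449 comparisons kept their direction and side of the threshold, 182 lost the call, 8 gained it and 9 changed sign. The sign changes were in Il10 and Cd80, which did not pass in any setting. Il10 (log2 fold change -0.14) ranged from -0.27 to 0.05 with 1 library left out, was at 0 with the length trend removed and at 0.14 without both number 1 libraries. Cd80 (-0.01) ranged from -0.07 to 0.08 with 1 library left out, and was at 0.02 without the low-count filter, 0.03 with the length trend removed and 0.04 with that and the replicate block. For both, the cause was not tested. For the 10 lists, 155 of 170 comparisons kept the call and 15 lost it, 10 of them with the estimated correlation. Counting error limits genes near 3 counts per library (0.153 to 0.196 CPM). In simulated counts, where far fewer genes changed than were called in the data, 20% of genes changed 1.5-fold were recovered.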

Other observations

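The 5 lists of this part, and the tests of a length trend in PBS replicate 1, of library size, of endotoxin, of the action of PTEN itself and of its phosphatase activity, were chosen only after the results were seen. The camera p-values of these lists were adjusted over the 5 lists alone. They describe the lists and are not independent evidence, since the lists share genes with the fixed lists already called. Components of pathogen sensing moved in opposite directions. Of 21 Toll-like receptors and adaptors, 10 rose, Tlr4, Tlr5 and Tlr13 fell and 8 did not pass (median log2 fold change 0.47; camera adjusted p = 0.0015; adjusted p = 0.25 with an estimated correlation). Tlr2 and Tlr1, which pair to bind lipoproteins, rose by log2 fold changes of 3.67 and 2.30, and the adaptor Myd88 by 1.33, while Tlr4, the endotoxin receptor, fell from 139 ± 47.4 to 64.7 ± 3.46 CPM (SD, n = 3; edgeR adjusted p = 0.0125). The call of Tlr4 was lost without PTEN replicate 1 (edgeR adjusted p = 0.0565) or PTEN replicate 3 (edgeR adjusted p = 0.054). Of 15 inflammasome components, 8 rose and Nlrp1b and Pycard fell (median 0.76; camera adjusted p = 0.0022; adjusted p = 0.24 with an estimated correlation), with Nlrp3 going from 104 ± 18.4 to 1411 ± 105 CPM. The call of Pycard, which encodes the ASC adaptor, was lost without PBS replicate 3 (edgeR adjusted p = 0.0643), PTEN replicate 2 (0.0859) or PTEN replicate 3 (0.0985).

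Inhibitors and co-stimulatory and checkpoint molecules changed as well. Of 14 cytokine signalling inhibitors, 9 rose and Pias3 and Socs6 fell (median log2 fold change 0.72; camera adjusted p = 0.0031; adjusted p = 0.24 with an estimated correlation), with Socs3 going from 5.86 ± 1.28 to 563 ± 12.8 CPM (SD, n = 3) and Socs1 from 1.80 ± 0.449 to 29.3 ± 4.6 CPM. Of 16 co-stimulatory and checkpoint ligands and receptors, 9 rose and Vsir, Havcr2, Tnfsf14 and Cd276 fell (median 0.71; camera adjusted p = 0.021; adjusted p = 0.24 with an estimated correlation). Cd274, which encodes PD-L1, rose from 12.6 ± 3.82 to 175 ± 10.9 CPM and Cd40 from 12.5 ± 2.24 to 382 ± 22.4 CPM, whereas Vsir, which encodes VISTA, fell from 296 ± 15.2 to 123 ± 3.95 CPM. Of 17 chemoattractant receptors, Fpr1, Fpr2, Ccrl2 and Cmklr1 rose and 7 fell (median -0.22; camera adjusted p = 0.61; adjusted p = 0.61 with an estimated correlation). The formyl peptide receptor gene Fpr1 rose from 1.85 ± 0.554 to 84.0 ± 10.1 CPM, and C5ar2 fell from 17.8 ± 2.90 to 3.96 ± 1.09 CPM.

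Inflammatory and interferon-stimulated genes were higher with PTEN. A gene length trend does not account for this, since 100% of the 102 called members of the proinflammatory, NF-kB, endotoxin-inducible and type I interferon lists still rose with the trend removed in the fit with the replicate block. Endotoxin in the added preparation would raise the endotoxin-inducible list, of which 27 of 27 members rose. An action of the PTEN protein itself could raise the same genes, since PTEN is the only labelled difference between the groups. The rise of 25 of 27 interferon-gamma and STAT1 targets favours neither. These explanations cannot be told apart here, because the samples include neither a heat-inactivated or mutant protein nor a matched endotoxin dose. Both may contribute, and an endotoxin assay of the preparation would bear on it.

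FOXO target genes were more often lower than higher, 11 against 4, but their list did not pass camera (adjusted p = 0.093; adjusted p = 0.72 with an estimated correlation). It passed as lower with fry (adjusted p = 0.03) and, with the preset correlation, without both number 1 libraries (adjusted p = 0.023), and its median of -0.46 lay at percentile 0.02 of 10000 random lists matched on expression, which ignore correlation between genes. A length trend does not account for the falls, since 100% of the 11 falling members kept at least 50% of their fall with the trend removed in the fit with the replicate block. Added PTEN acting inside the cells as a phosphatase that restrains PI3K and AKT would release these genes and raise them. The median gives no sign of such a rise, but it restates the pattern, members went both ways and the tests of the list disagree, so whether PTEN acted in this way stays open.

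PBS replicate 1 stood apart from PBS replicates 2 and 3. GC content took 5.59% of the variance of its log2 CPM deviations, too little to account for the gap, and its total of 18533017 counts lay within the range of the other 5 libraries. A curve on gene length took 45.6%, which is consistent with a difference in RNA integrity, fragmentation or library preparation. It took 35% and 37.2% in PBS replicates 2 and 3, with the opposite sign, because each library was compared with the others of its group and replicate 1 is among them, and 21.4% in PTEN replicate 1. No biological explanation was tested, since the labels give no difference among the PBS libraries, and what lies behind the length trend stays open.

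The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For changed genes the real split gave 3527 and the highest of the others 0 by edgeR, with 18 to 666 genes at an unadjusted p under 0.05, so 1 of the 10 splits gave as many. Of the 4 splits that part all 3 numbered pairs, the other 3 also gave 0. Every split other than the real one mixes PBS and PTEN libraries on both sides, which turns most of the group difference into spread within a side. Calls were therefore unlikely in advance, and the counts of 0 lend no support to the 3527. For gene lists the real split gave 10 and the highest other 14, with PBS replicate 1 and PTEN replicates 2 and 3 on one side, and 8 of the 10 splits gave as many lists as the real one. Each split other than the real one also keeps part of the difference between the groups. The share of splits therefore does not show what the number of lists called with the preset correlation measures.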
